A study of Mus musculus with 39 samples.

How the data were processed

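Hind paw punch biopsies and lumbar L3 to L5 dorsal root ganglia (DRG) of C57 mice aged 8 to 12 weeks had been sequenced after paclitaxel or vehicle. Libraries were stranded mRNA libraries read single-end over 50 bases, per the labels' protocols. Reads were sorted with bcl2fastq, aligned to mm9 with TopHat2 and counted with HTSeq, per the submitters' processing notes. The notes give no tool versions, gene annotation or strand setting for counting. The deposited values are raw counts per gene symbol with no normalization, 1 file for each of the 39 libraries, each with 22609 genes and 5 summary lines. The summary lines name no gene and were left out of library sizes and tests. Reads outside annotated genes made up 13.91% to 21.55% of uniquely placed reads, reads touching more than 1 gene 0.21% to 0.75%, and there were 45.18 to 95.78 reads without a unique place per 100 with one.

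Groups were taken from the labels: 8 paw groups (24 libraries) and 5 DRG groups (15 libraries), 3 libraries each. Libraries held 16781618 to 24598926 gene reads in paw and 19049166 to 26136854 in DRG. Every pair of libraries of the same tissue was compared, and none were identical or as close as 2 samplings of 1 library (chi-square per degree of freedom at least 8.25 in paw and 4.83 in DRG). The sex on each label was checked against Xist and 4 Y-linked genes.

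Each tissue was fitted on its own with edgeR 4.0.16 (quasi-likelihood F test, 1 coefficient per group, TMM size factors from 0.94 to 1.08 in paw and from 0.98 to 1.02 in DRG) in R 4.3.3. The filter filterByExpr left 15346 genes in paw and 15577 in DRG. The common biological coefficient of variation was 0.244 in paw and 0.133 in DRG, with 16 and 10 residual degrees of freedom. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Values after ± are standard errors.

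For gene lists, 39 lists written from general knowledge covered neurons and nerve injury, glia, skin and hair, immune cells, cell division, metabolism, stress, blood, muscle and sex chromosomes. Of their 790 genes, 787 were in the files. Lists with at least 5 measured members were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over lists, then again with an estimated correlation and with fry. Members are counted as called over all genes and as called when adjusted over the list alone.

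Named genes were chosen by a rule: the 6 largest rises and falls among called genes with a mean log2 CPM of at least 1 and libraries that did not overlap, up to 4 members of each passing list with the smallest p in the direction of the list, a short set of genes chosen beforehand for each tissue, and the sex-linked genes. Not every gene the rule gives is reported here. Symbols were matched to a RefSeq table (20043 current and 2327 older symbols). Exons on either strand were compared for 20284 genes (89.7%), with an overlap counted from 50 shared bases, and 294 genes had a named pseudogene. Where all libraries of a group had 0 reads, a fold was given as a bound against a floor of 3 counts per library. Bounds cover counting error only.

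The test was tested on simulated data with the real means, library sizes and 200 genes changed. A further list of genes was raised by 0.5 log2 and left out of the counts below. Raised or lowered by 1 log2, 70.1% of changed genes were recovered in paw female day 2 against vehicle, 76.1% in paw male day 15 against day 2 and 92.5% in the DRG comparisons of female day 2 with vehicle and male day 6 with day 2. At 0.5 log2 these shares were 31.3%, 10.4%, 49.3% and 46.3%. In these simulations edgeR called 3 to 10 unchanged genes and DESeq2 22 to 32. Each gene was drawn independently, without the shared differences in tissue content of the real libraries, so these counts and shares may not carry over to them.

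Alternatives were relative-log-expression size factors, no low-count filter, DESeq2 1.42.0, the replicate number as a block, only the compared groups in the fit, each library of the compared groups left out in turn and, added later, the mean level of skeletal muscle genes as a covariate. Replicates with the same number deviated together, with every pair's correlation over 0.1, in paw for female day 2 (0.21 to 0.65) and for male days 2, 6 and 15 (0.1 to 0.84, 0.34 to 0.76 and 0.34 to 0.66) against vehicle, and in DRG for male day 6 against day 2 (0.28 to 0.46) and against vehicle (0.19 to 0.23). That pairing comes from the values alone, since the labels do not say what a number marks. A male and a vehicle female cannot be 1 animal. In paw, replicate 2 had the lowest mean skeletal muscle level in vehicle and in each of these treated groups.

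Agreement between 2 comparisons was measured by the correlation and covariance of log2 changes, by genes called in both and by the number expected from independence (the product of the 2 counts over all genes). Correlations and covariances were set beside simulated ones with the same shared libraries and no effects. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The series text speaks of controls for both sexes, but male vehicle libraries were not analysed here.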

Results

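Paclitaxel is a cancer drug that binds microtubules and often leaves patients with painful nerve damage. Expression was followed by poly(A) RNA sequencing in hind paw skin and in lumbar dorsal root ganglia (DRG, which hold the cell bodies of sensory neurons) of C57 mice given 2 injections of paclitaxel at 3 mg/kg. Days were counted from the last injection. Paw skin was taken on days 2, 6, 16 and 26 in females and on days 2, 6 and 15 in males, and DRG on days 2 and 6 in both sexes. Females given vehicle and sampled 1 day later gave the control libraries of both tissues, and vehicle males were not analysed here. The 39 libraries made 13 groups of 3. The labels do not state that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. Female days against vehicle, male days against male day 2, the sexes at matched days, sex by time and the agreement between comparisons, with the gene lists and the edgeR test, were fixed before the data were examined. Comparisons among female days and of treated males with vehicle females were added afterwards.

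Libraries held 16781618 to 26136854 reads assigned to genes, and 16671 to 17638 of 22609 genes had a read. Xist, the RNA that silences an X chromosome in female cells, ran from 184 to 1750 CPM (counts scaled to library size) in females and from 0.191 to 0.939 CPM in males. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty ran from 11.8 to 129 CPM in males and had at most 2 reads in any female library, so the sex of all 39 libraries matched its label. The libraries fell into 2 sets by a technical measure. Reads that touched more than 1 gene made up 0.21% to 0.30% of uniquely placed reads in the 18 libraries of paclitaxel females and 0.54% to 0.75% in the other 21, which were vehicle females and paclitaxel males. In DRG, reads outside annotated genes ran from 14.97% to 16.31% in the first set and from 17.29% to 18.03% in the second, while in paw the sets overlapped (13.91% to 18.66% and 17.54% to 21.55%). In paw, the second principal component (25.1% of variance) put all 12 libraries of paclitaxel females on one side and the other 12 on the other. Comparisons of paclitaxel females with vehicle or with males therefore cross from one set to the other, and in them treatment or sex and library set cannot be told apart.

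**Figure D1:**
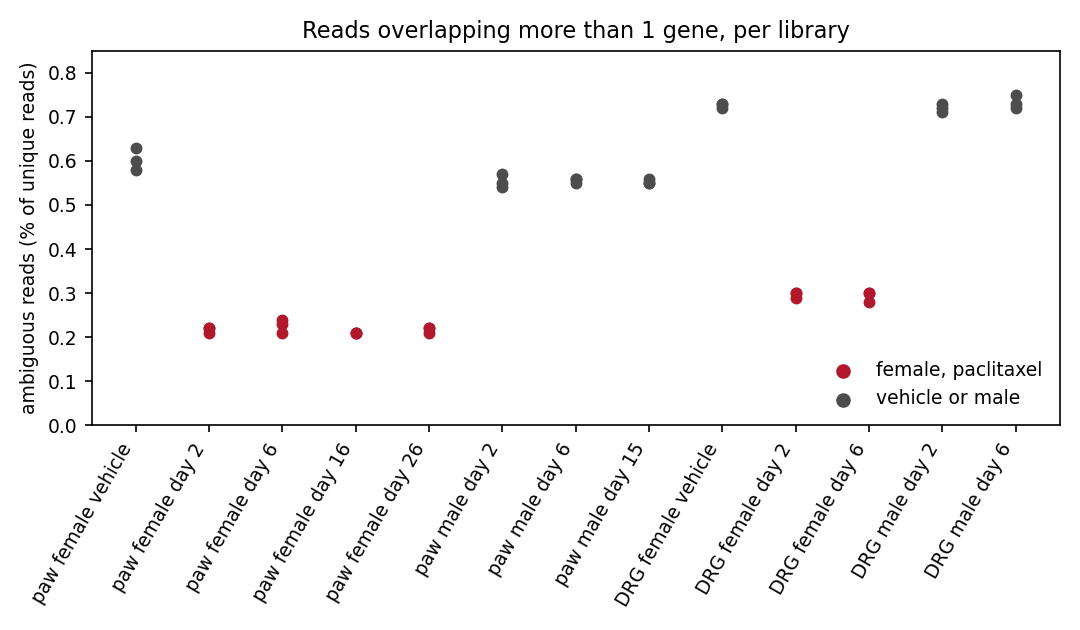
Share of uniquely placed reads that touched more than 1 gene, for each library, by tissue and group. Libraries of paclitaxel females lay below all others.

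To find what set treated female skin apart 2 days after paclitaxel, paw libraries of that day were compared with vehicle. Genes of the hair shaft were lower: Krtap7-1 and Krtap8-1, which encode proteins that pack between hair keratins, and the hair keratin genes Krt33a, Krt33b and Krt34 had 0 reads in all 3 treated libraries. Their vehicle libraries held up to 161, 140, 117, 111 and 61 reads, so they were at least 42.5-fold, 32.1-fold, 33.1-fold, 28-fold and 18.1-fold lower (adjusted p = 0.003, 0.00819, 0.00755, 0.00349 and 0.00327). Krt31 had at most 1 read in a treated library against up to 173 in vehicle (adjusted p = 0.00206). Of 26 hair follicle genes, 13 fell (16 when adjusted over the list alone), with a median log2 change of -3.22, or -2.91 with genes at 0 held at 3 counts per library (camera adjusted p = 3.33e-07, 0.976 with an estimated correlation). Genes of mitosis fell with them, among them the proliferation marker Mki67 (log2 change -1.71 ± 0.29, where ± gives the standard error, adjusted p = 0.000247), the spindle-bound Hmmr (-1.05 ± 0.23, adjusted p = 0.00212) and the kinetochore gene Cenpf (-1.43 ± 0.31, adjusted p = 0.00193, no longer called when the groups were fitted alone). In all, 9 of 30 mitosis genes fell (12 over the list alone, median -0.39, camera adjusted p = 0.00168, 0.976 with an estimated correlation, 0.149 with the skeletal muscle level as a covariate). The DNA replication list had a median of 0. Genes of mitochondrial respiration rose, 23 of 32 with 1 falling (26 and 1 over the list alone, median 0.63, camera adjusted p = 5.28e-07, 0.976 with an estimated correlation). Among these were Cox4i1 of complex IV (1.06 ± 0.14, adjusted p = 2.58e-05), Ndufv1 of complex I (1.01 ± 0.17, adjusted p = 0.000267) and Uqcrc1 of complex III (0.75 ± 0.13, adjusted p = 0.000311). In treated male paw, which lies in the same library set as vehicle, the respiration medians against vehicle were 0.01, -0.09 and 0.08 on days 2, 6 and 15.

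Matrix genes rose in the same female paw libraries on day 2, 12 of 29 fibroblast genes (18 over the list alone, median 0.72, camera adjusted p = 0.00168, 0.976 with an estimated correlation). Among these were the collagen gene Col1a2 (1.35 ± 0.32, adjusted p = 0.00356), Sparc, whose product binds collagen (0.84 ± 0.21, adjusted p = 0.00475), and Col6a3 (1.18 ± 0.30, adjusted p = 0.00651). Of 25 macrophage genes, 1 rose (0 over the list alone, median 0.56, camera adjusted p = 0.0364, 0.976 with an estimated correlation). Muscle content differed between biopsies, with a mean skeletal muscle level of 6.46 log2 CPM in vehicle and 9.52 on day 2 (list median 1.64, bone and cartilage 1.45, no muscle gene called). It was 4.53, 8.21 and 7.88 on days 6, 16 and 26. With that level as a covariate the fibroblast and macrophage lists gave adjusted p = 0.108 and 0.445, with medians of 0.48 and 0.28, and the respiration median was 0.43. The largest rises included Rpl37, a ribosomal protein gene (3.71 ± 0.22, adjusted p = 6.01e-10), and Tpt1, which had at most 2 reads in vehicle and up to 745 in treated libraries (adjusted p = 2.39e-10). Several of the largest rises are uncertain: Tpt1 has 6 named pseudogenes, and Rpl5 (3.42 ± 0.22, adjusted p = 2.8e-09) and Phospho1 (3.61 ± 0.20, adjusted p = 2.79e-10) share bases with the opposite-strand genes Fam69a and Zfp652. Epidermal genes chosen beforehand did not pass: Krt14 gave 0.20 ± 0.20 (adjusted p = 0.47), Krt1 -0.02 ± 0.33 (adjusted p = 0.966), Krt16 0.08 ± 0.60 (adjusted p = 0.935) and Cd207 of Langerhans cells -0.60 ± 0.27 (adjusted p = 0.0994). The inflammatory Il1b had at most 22 reads in a library (0.71 ± 1.44, adjusted p = 0.738). Of 15346 genes tested, 2164 rose and 2290 fell, and 992 of these moved by more than 1 log2. With these groups fitted alone, 2019 genes passed. Libraries of the groups did not overlap at 5898 genes (38.4%, where 10% would be met by chance).

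On day 6 hair genes were still low in female paw, while genes of DNA synthesis had risen above vehicle. Gprc5d, a receptor gene of the hair-forming cells, had at most 4 reads against up to 75 in vehicle (log2 change -4.81 ± 1.21, adjusted p = 0.00549), and Krtap3-1 had at most 6 against up to 162 (-5.81 ± 1.18, adjusted p = 0.00101). Krtap7-1 had at most 1 read (adjusted p = 0.00378). The list had 8 of 26 genes lower, over all genes and over the list alone (median -1.52, camera adjusted p = 0.00208, 0.948 with an estimated correlation). Of 26 replication genes 10 rose (11 over the list alone, median 0.46, camera adjusted p = 0.00208, 0.948 with an estimated correlation). Among these were Gins1 of the replication fork (0.99 ± 0.22, adjusted p = 0.00208) and the thymidine kinase gene Tk1 (0.83 ± 0.13, adjusted p = 9.87e-05, sharing bases with the opposite-strand Afmid). Mki67 was lower (-1.23 ± 0.29, adjusted p = 0.00332), while the mitosis list did not pass (2 of 30 up and 3 down, the same over the list alone, median 0.22, camera adjusted p = 0.518, 0.948 with an estimated correlation). Immediate early genes, which cells switch on within minutes of a stimulus, were lower: Fos fell by 3.32 ± 0.61 (adjusted p = 0.000441), Egr1 by 2.04 ± 0.41 (adjusted p = 0.000856), Egr3 by 0.97 ± 0.18 (adjusted p = 0.000601) and Zfp36, an mRNA decay factor, by 1.31 ± 0.24 (adjusted p = 0.000417). They made up 4 of the 7 of 15 list members that fell (7 over the list alone, median -0.74, camera adjusted p = 0.0178, 0.948 with an estimated correlation). Respiration genes rose again, 14 of 32 with 1 falling (15 and 1 over the list alone, median 0.33, camera adjusted p = 0.00208, 0.948 with an estimated correlation), including Cox4i1 (0.94 ± 0.14, adjusted p = 6.65e-05) and Ndufa4 (0.87 ± 0.16, adjusted p = 0.000369). Krt14, the basal keratinocyte keratin, rose by 0.58 ± 0.20 (adjusted p = 0.0359), a call lost without vehicle replicate 1 or 3, without day 6 replicate 1 or 3, and with the groups fitted alone. On this day 2460 genes rose and 2067 fell, 920 by more than 1 log2, and 6570 genes (42.8%, against 10% by chance) had libraries that did not overlap.

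Of the lists that passed in female paw on day 16 after paclitaxel, mitosis genes had the smallest camera adjusted p. The hair list no longer passed (median 1.51, 4 rising, 1 over the list alone, camera adjusted p = 0.239). Replication genes, the other list of dividing cells, had a median of 0.09. Of 30 mitosis genes 19 fell (23 over the list alone, median -0.65, camera adjusted p = 4.67e-07, 0.834 with an estimated correlation). Among these were Mki67 (-1.2 ± 0.29, adjusted p = 0.00546), Hmmr (-0.98 ± 0.23, adjusted p = 0.00469) and Nusap1 of the spindle (-1.13 ± 0.16, adjusted p = 6.87e-05, sharing bases with the opposite-strand Oip5). Immediate early genes were still low, 6 of 15 over all genes and over the list alone (median -0.30, camera adjusted p = 0.0221, 0.834 with an estimated correlation), with Fos at -3.48 ± 0.62 (adjusted p = 0.000474), Egr1 at -2.27 ± 0.41 (adjusted p = 0.000543) and Zfp36 at -1.53 ± 0.24 (adjusted p = 0.000153). Krt16, a keratin that epidermis makes when wounded or stressed, rose by 2.79 ± 0.63 (adjusted p = 0.00364), and Chi3l1, which encodes a secreted protein of inflamed tissue, by 3.45 ± 0.47 (adjusted p = 3.28e-05). Respiration genes rose in 12 of 32 cases, with 1 falling (14 and 1 over the list alone, median 0.39, camera adjusted p = 0.00543, 0.834 with an estimated correlation), again with Cox4i1 (0.76 ± 0.14, adjusted p = 0.00075) and Ndufa4 (0.75 ± 0.16, adjusted p = 0.00179). Fibroblast genes rose in 2 of 29 cases, over all genes and over the list alone (median 0.55, camera adjusted p = 0.0235, 0.834 with an estimated correlation). With muscle as a covariate the fibroblast, respiration and immediate early lists gave adjusted p = 0.0924, 0.0675 and 0.0758. Counts were 1745 up and 1586 down, with 5675 genes (37%, against 10% by chance) whose libraries did not overlap.

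On day 26, the last day sampled, mitosis genes remained low in female paw, 11 of 30 (12 over the list alone, median -0.46, camera adjusted p = 0.00026, 0.994 with an estimated correlation). Among these were the kinase gene Aurka (-1.03 ± 0.24, adjusted p = 0.00383) and Nusap1 (-0.80 ± 0.16, adjusted p = 0.00146). Cornified envelope genes of stressed epidermis were below vehicle: Sprr1b gave -1.31 ± 0.24 (adjusted p = 0.000618), Lce3c -1.14 ± 0.26 (adjusted p = 0.00327), and Sprr2e had at most 4 reads against up to 65 (-4.53 ± 1.1, adjusted p = 0.00616). Over the list of stressed keratinocyte genes 4 of 20 fell, over all genes and over the list alone (median -0.60, camera adjusted p = 0.0476, 0.994 with an estimated correlation). That list gave adjusted p = 0.0602 with relative-log-expression size factors, 0.0564 with the replicate number as a block and 0.153 with muscle as a covariate. Its median had been -0.54, 0.21 and 0.67 on days 2, 6 and 16. Respiration genes rose in 10 of 32 cases, with 1 falling (11 and 1 over the list alone, median 0.32, camera adjusted p = 0.0476, 0.994 with an estimated correlation). They gave adjusted p = 0.0582 with relative-log-expression size factors and 0.188 with muscle as a covariate. Msx1, a homeobox gene expressed in nail and hair-forming skin, rose by 2.73 ± 0.24 (adjusted p = 1.95e-07). Dcdc2b, which encodes a doublecortin-domain protein of the kind that binds microtubules, fell by 4.22 ± 0.25 (adjusted p = 8.9e-10). Its earlier values were -3.73 ± 0.24 on day 2 (adjusted p = 2.61e-09, chosen there after its value was seen), -4.2 ± 0.25 on day 6 (adjusted p = 6.72e-10) and -4.01 ± 0.25 on day 16 (adjusted p = 1.4e-09). In all, 1689 genes rose and 1444 fell, and libraries did not overlap at 6053 genes (39.4%, against 10% by chance).

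**Figure D2:**
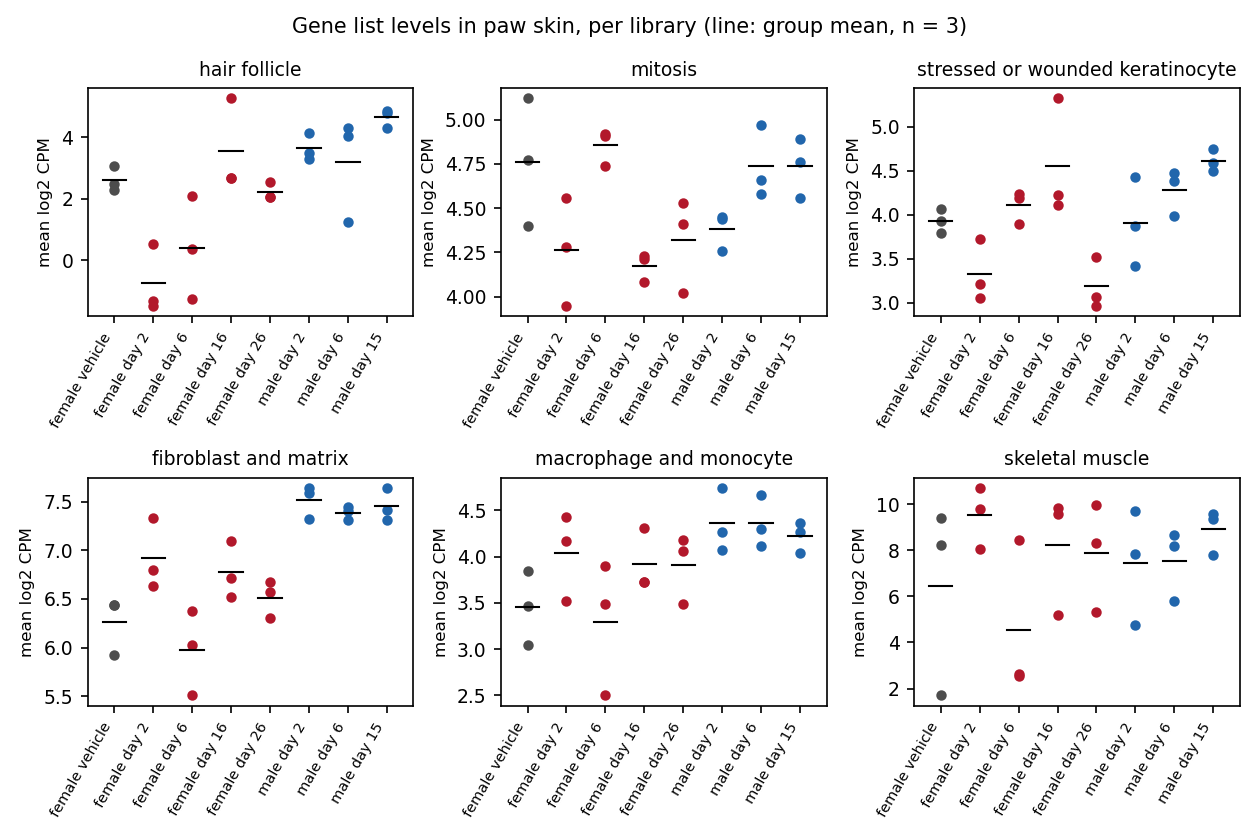
Mean log2 CPM of 6 gene lists in each paw library, by group. Each point is 1 library.

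In DRG, which hold the cell bodies of the neurons that paclitaxel harms, treated females were compared with vehicle 2 days after the last injection. Ion channel genes that set neuronal firing were lower: Scn10a, the sodium channel of nociceptors, gave -0.69 ± 0.10 (adjusted p = 4.5e-05), the potassium channel gene Kcna1 -0.81 ± 0.09 (adjusted p = 4.92e-06) and the calcium channel gene Cacna1a -0.51 ± 0.05 (adjusted p = 8.27e-07). Of 30 such genes 15 fell and 2 rose, over all genes and over the list alone (median -0.38, camera adjusted p = 0.00896, 0.575 with an estimated correlation). Calca, which encodes the pain peptide CGRP, rose by 0.56 ± 0.08 (adjusted p = 3.15e-05), and Gal, the galanin gene induced by nerve injury, by 0.86 ± 0.18 (adjusted p = 0.00124). The injury factor Atf3 gave 0.39 ± 0.17 (adjusted p = 0.0613), Trpv1, the capsaicin receptor gene, 0.17 ± 0.09 (adjusted p = 0.139) and the chemokine gene Ccl2 0.06 ± 0.48 (adjusted p = 0.922). As a list, nerve injury genes had 9 rises and 4 falls of 24 (median 0.24, camera adjusted p = 0.413). Tubulins and their partners, the targets of the drug, had 4 rises and 9 falls of 22 (median -0.13, camera adjusted p = 0.797). Cd68, a lysosomal marker of macrophages, fell by 1.2 ± 0.21 (adjusted p = 0.000358). Matrix genes fell in 17 of 28 cases, with 2 rising (18 and 2 over the list alone, median -0.38, camera adjusted p = 0.00896, 0.96 with an estimated correlation). Among these were Bgn (-1.13 ± 0.13, adjusted p = 9.71e-06), Dcn (-0.67 ± 0.12, adjusted p = 0.000484) and Col6a1 (-0.45 ± 0.09, adjusted p = 0.000853). Tissue content differed between samples, with mean skeletal muscle levels of 3.15 to 4.32 log2 CPM in vehicle libraries and 4.25, 4.27 and 8.69 on day 2.

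Respiration genes rose in these DRG too, 28 of 32 with 1 falling, over all genes and over the list alone (median 0.48, camera adjusted p = 1.94e-09, 0.96 with an estimated correlation). Among these were Cox4i1 (0.96 ± 0.06, adjusted p = 1.41e-08), Sdhc of complex II (0.85 ± 0.07, adjusted p = 6.45e-07) and Ndufv1 (0.79 ± 0.07, adjusted p = 4.21e-07). Genes of cornified skin, which ganglia are not known to make, also rose. Lor, the loricrin gene, went from at most 35 reads in vehicle to as many as 468 (4.04 ± 0.20, adjusted p = 2.16e-09), Krt2 rose by 3.25 ± 0.18 (adjusted p = 7.6e-09), Krt9 of palm and sole skin by 3.02 ± 0.20 (adjusted p = 3.79e-08) and Krt10 by 2.74 ± 0.18 (adjusted p = 4.6e-08). Of 21 differentiated keratinocyte genes 19 rose (20 over the list alone, median 2.39, camera adjusted p = 2.18e-15, 0.114 with an estimated correlation). Some single genes fell: Myh6, a cardiac myosin gene, by 5.69 ± 0.56 (adjusted p = 1.92e-06), Pla2g4b, a phospholipase gene, by 3.94 ± 0.16 (adjusted p = 2.41e-10), and Slc18a2, the vesicular monoamine transporter gene, by 3.57 ± 0.28 (adjusted p = 2.55e-07). Tmem140, a membrane protein gene, rose by 4.48 ± 0.24 (adjusted p = 5.4e-09). Of 15577 genes tested in DRG, 4018 rose and 3740 fell, and 8811 (56.6%, against 10% by chance) had libraries that did not overlap.

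On day 6, the DRG of treated females were compared with vehicle again. Ctss, a lysosomal protease gene of macrophages, fell by 0.90 ± 0.09 (adjusted p = 2.68e-06), the complement genes C1qa and C1qb by 0.92 ± 0.11 and 0.72 ± 0.11 (adjusted p = 1.83e-05 and 8.85e-05) and Cd68 by 1.32 ± 0.21 (adjusted p = 0.000203), among 9 of 25 macrophage genes (9 over the list alone, median -0.52, camera adjusted p = 0.00194, 0.675 with an estimated correlation). H2-Aa, which presents antigen to helper T cells, fell by 0.56 ± 0.15 (adjusted p = 0.00841), and Cd74, its chaperone, by 0.63 ± 0.13 (adjusted p = 0.00106), among 7 of 15 antigen presentation genes (8 over the list alone, median -0.40, camera adjusted p = 0.019, 0.675 with an estimated correlation). T and NK cell genes fell in 4 of 10 cases (4 over the list alone, median -0.77, camera adjusted p = 0.0155), 1 of which, Cd247 (-5.24 ± 0.33, adjusted p = 3.24e-08), shares bases with the opposite-strand Pou2f1 and is uncertain. This list gave adjusted p = 0.0519 by DESeq2 and 0.547 with an estimated correlation. Mitosis genes fell in 11 of 29 cases (11 over the list alone, median -0.60, camera adjusted p = 0.0156, 0.675 with an estimated correlation), with the checkpoint kinase gene Bub1 at -1.43 ± 0.38 (adjusted p = 0.00733). Matrix genes fell in 13 of 28 cases (14 over the list alone, median -0.37, camera adjusted p = 0.00242, 0.675 with an estimated correlation), with Bgn at -1.12 ± 0.13 (adjusted p = 1.21e-05), Col6a2 at -0.46 ± 0.09 (adjusted p = 0.000897) and the tenascin gene Tnc at -1.05 ± 0.22 (adjusted p = 0.00168).

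Respiration and keratinocyte genes in female DRG stayed up on day 6, with 25 of 32 respiration genes higher and 2 lower (28 and 2 over the list alone, median 0.41, camera adjusted p = 1.12e-07, 0.675 with an estimated correlation) and 20 of 21 keratinocyte genes higher (20 over the list alone, median 2.37, camera adjusted p = 7.04e-18, 0.0804 with an estimated correlation). Cox4i1 rose by 0.86 ± 0.06 (adjusted p = 4.03e-08), Lor by 4.02 ± 0.20 (adjusted p = 2.56e-09) and Krt2 by 3.28 ± 0.18 (adjusted p = 7.2e-09). Calca was still up by 0.49 ± 0.08 (adjusted p = 0.000126), and Gal gave 0.48 ± 0.18 (adjusted p = 0.0441), a call lost without any single library of either group, with no low-count filter and with muscle as a covariate. Scn10a no longer passed (-0.24 ± 0.10, adjusted p = 0.059), and neither did Atf3 (0.08 ± 0.17, adjusted p = 0.742) or Trpv1 (0.00 ± 0.09, adjusted p = 0.973). The nerve injury list had 8 rises and 3 falls (median 0.08, camera adjusted p = 0.643) and the tubulin list 4 and 9 (median 0.01, camera adjusted p = 0.769). In total 3617 genes rose and 2852 fell, and libraries did not overlap at 8177 genes (52.5%, against 10% by chance).

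Because days within treated females do not cross between the library sets, they were then compared with each other. Paw hair genes ran higher on day 16 than on day 2. Mean hair list levels were -0.75 log2 CPM on day 2 (standard deviation 1.11), 0.41 on day 6 (1.68), 3.54 on day 16 (1.5) and 2.22 on day 26 (0.28), against 2.62 (0.41) in vehicle. From day 2 to day 16, Krtap7-1, Krt33a and Krtap8-1 went from 0 reads to as many as 760, 847 and 738, at least 132-fold, 127-fold and 127-fold up (adjusted p = 0.00951, 0.0157 and 0.0164). The list had 14 of 26 genes higher (22 over the list alone, median 4.56, also at the bound, camera adjusted p = 3.77e-30, 0.172 with an estimated correlation). The stress keratin gene Krt16 rose over the same days by 2.71 ± 0.63 (adjusted p = 0.0375), among 5 of 20 stressed keratinocyte genes (15 over the list alone, median 1.23, camera adjusted p = 4.08e-14, 0.172 with an estimated correlation). Of 20 antioxidant genes 3 rose (4 over the list alone, median 0.15, camera adjusted p = 0.0114, 0.403 with an estimated correlation). Gclc of glutathione synthesis rose by 0.58 ± 0.10 (adjusted p = 0.00818) and the cystine transporter gene Slc7a11 by 1.52 ± 0.32 (adjusted p = 0.0246). The chemokine gene Ccl20 rose by 2.72 ± 0.51 (adjusted p = 0.0122). Counts were 187 up and 40 down, and 507 in all by DESeq2. All these calls were lost without day 2 replicate 3, which left 0 genes, all but that of Krtap7-1 without day 16 replicate 3, and those of Krt33a, Krtap8-1, Krt16 and Slc7a11 without day 2 replicate 2. Other omissions left 476 (day 2 replicate 1), 125 (day 2 replicate 2) and 44 (day 16 replicate 3), and the groups fitted alone gave 0.

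Female paw on day 6 was set against day 2 in the same way, which gave 63 genes up and 71 down. The replication factor gene Cdc6 rose by 0.90 ± 0.20 (adjusted p = 0.0462) and the epidermal cytokine gene Il1f6 by 0.85 ± 0.17 (adjusted p = 0.0351), while Col6a3 fell by 1.30 ± 0.30 (adjusted p = 0.0487) and Fmod, the fibromodulin gene, by 2.12 ± 0.48 (adjusted p = 0.0487). The mitosis list had 1 of 30 genes higher (24 over the list alone, median 0.57, camera adjusted p = 2.64e-13) and the fibroblast list 1 of 29 lower (26 over the list alone, median -0.79, camera adjusted p = 3.74e-15), each adjusted p = 0.573 with an estimated correlation. Muscle content also ran lower on day 6, with a mean muscle list level of 4.53 log2 CPM against 9.52 on day 2, and with muscle as a covariate 0 genes passed. This comparison moved with single libraries. It called 80, 2063 and 0 genes without day 2 replicates 1, 2 and 3, and 0, 1060 and 2 without day 6 replicates 1, 2 and 3. All 4 genes named here lost their calls without day 2 replicates 1 or 3 and without day 6 replicates 1 or 3. No low-count filter left 47 genes, DESeq2 called 1463, and the groups fitted alone 0.

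Female paw on day 26 was set against day 16 as well. Chi3l1 fell by 3.65 ± 0.48 (adjusted p = 0.000974), the proton pump gene Atp12a by 3.06 ± 0.48 (adjusted p = 0.00553), Krt16 by 3.47 ± 0.66 (adjusted p = 0.0179), Gclc by 0.61 ± 0.10 (adjusted p = 0.00728), Ccl20 by 3.12 ± 0.55 (adjusted p = 0.0119) and the clock gene Per2 by 2.60 ± 0.43 (adjusted p = 0.00654). Fos rose by 2.63 ± 0.60 (adjusted p = 0.0403). The stressed keratinocyte list fell in 3 of 20 cases (16 over the list alone, median -1.03, camera adjusted p = 2.13e-16) and the antioxidant list in 3 of 20 (5 over the list alone, median -0.21, camera adjusted p = 1.02e-05), each adjusted p = 0.055 with an estimated correlation. Of these genes only Chi3l1 and Atp12a kept their calls without any 1 library. Krt16, Gclc and Ccl20 lost theirs without day 16 replicate 3 or day 26 replicate 1, Krt16 without day 26 replicate 3, Ccl20 and Per2 without day 26 replicate 2, Per2 without day 26 replicate 1, and Fos without any of the 6 libraries. In all 77 genes rose and 86 fell, and 41, 25, 12, 27 and 54 passed without day 16 replicates 1 and 3 and day 26 replicates 1, 2 and 3. DESeq2 called 409, the muscle covariate 355 and the groups fitted alone 0. Day 26 against day 2 gave 0 genes, with 1905 at unadjusted p < 0.05 and 249 by DESeq2. Without day 2 replicate 1 it gave 259 genes, without day 26 replicate 3 it gave 3, and with the groups fitted alone 1.

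In female DRG, days 2 and 6 differed in 11 genes up and 17 down. The synaptic genes Cacng2 and Gabra2 fell by 1.11 ± 0.13 and 1.00 ± 0.13 (adjusted p = 0.00705 and 0.00812), and these 2 calls were kept without any 1 library. Scn11a, a sodium channel gene of nociceptors, rose by 0.51 ± 0.09 (adjusted p = 0.0485), and Mrgprd, a receptor gene of nociceptors that end in the epidermis, by 0.54 ± 0.09 (adjusted p = 0.035). Ctss fell by 0.62 ± 0.09 (adjusted p = 0.0163). Ion channel genes as a list moved back up, 2 of 30 (9 up and 1 down over the list alone, median 0.24, camera adjusted p = 1.75e-09), and kept the call at adjusted p = 0.024 with an estimated correlation. The interferon list had 0 of 32 genes called (10 falling over the list alone, median -0.72, camera adjusted p = 3.07e-13, 0.376 with an estimated correlation). The day 2 libraries differed among themselves, with mean levels of 2.86 to 4.51 log2 CPM for interferon, -0.02 to 3.92 for central glia, 4.25 to 8.69 for skeletal muscle and 1.8 to 4.3 for adipocyte genes. Counts moved to 13, 84 and 97 without day 2 replicates 1, 2 and 3, and to 4 and 951 without day 6 replicates 2 and 3. Scn11a lost its call without day 2 replicate 1 or day 6 replicate 1 or 2, Mrgprd without day 2 replicate 1 or day 6 replicate 2, and Ctss without day 6 replicate 2. DESeq2 called 214 genes and the groups fitted alone 0.

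Male days were compared with male day 2, since no male vehicle was analysed. In paw, day 6 gave 0 genes (345 at unadjusted p < 0.05, 0 by DESeq2) and day 15 gave 0 (629 at unadjusted p < 0.05, 2 by DESeq2, 1 with the groups fitted alone). Libraries did not overlap at 6% and 9.9% of genes, where chance gives 10%. The inflammatory genes S100a9 and Il1b had values of 4.70 ± 1.78 and 4.38 ± 1.28 on day 6 and 6.64 ± 1.85 and 3.73 ± 1.28 on day 15, each at adjusted p = 1.0. No list passed with an estimated correlation. Mitosis genes had a median of 0.34 on day 6 (0 called, 3 rising over the list alone, camera adjusted p = 5.93e-24, 0.511 with an estimated correlation) and of 0.33 on day 15 (0 called, 3 rising over the list alone, camera adjusted p = 1.6e-19, 0.181 with an estimated correlation). By day 15 the clock list had a median of -0.25 (0 called, 3 falling over the list alone, camera adjusted p = 4.57e-05, 0.0598 with an estimated correlation), with the clock gene Per3 at -0.81 ± 0.14 (adjusted p = 0.184). Cytokine and antigen presentation lists had medians of 0.42 and 0.35 (0 called in each, 0 and 1 over the lists alone, camera adjusted p = 2.12e-07 and 2.25e-08, adjusted p = 0.0769 and 0.181 with an estimated correlation). Of the lists tested, 8 passed on day 6 and 17 on day 15 at the preset correlation alone.

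In male DRG, day 6 gave 0 genes against day 2 (920 at unadjusted p < 0.05, 9 by DESeq2), and libraries did not overlap at 14% of genes, against 10% by chance. Myelinating Schwann cell genes had a median of -0.28 over 17 genes (0 called, 12 falling over the list alone, camera adjusted p = 5.24e-22, 0.12 with an estimated correlation). Pmp22 and Mbp, which encode proteins of the myelin sheath, gave -0.28 ± 0.08 and -0.27 ± 0.07 (both adjusted p = 0.626). The injury genes Atf3 and Ecel1 gave -0.67 ± 0.17 and -1.58 ± 0.40 (both adjusted p = 0.626), and their list had a median of -0.14 (0 called, 2 falling over the list alone, camera adjusted p = 0.00291, 0.633 with an estimated correlation). Keratinocyte genes had a median of 0.52 (0 called, 4 rising over the list alone, camera adjusted p = 2e-11, 0.121 with an estimated correlation). In all, 13 lists passed, 1 up and 12 down, and none with an estimated correlation.

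**Figure D3:**
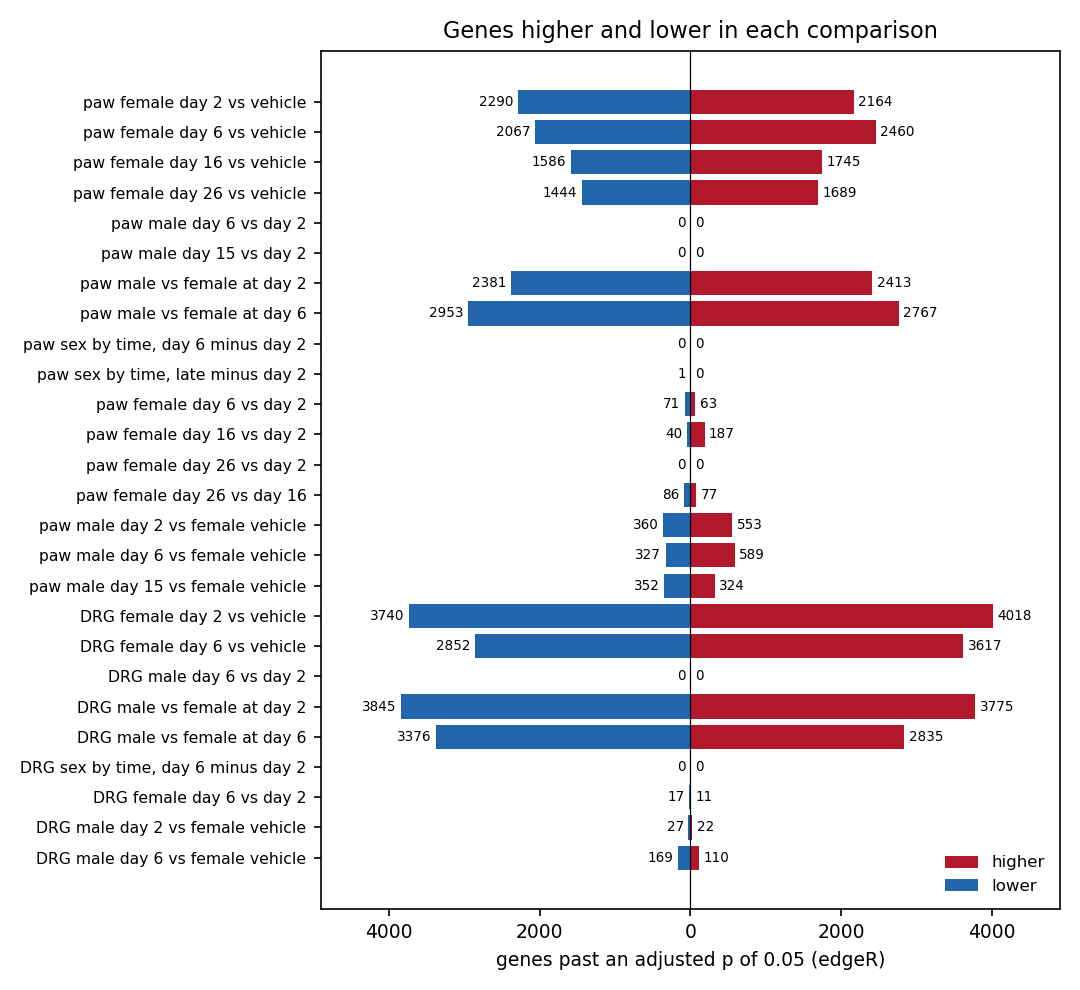
Number of genes called up and down in each comparison. Comparisons of treated females with vehicle or with males hold the largest counts.

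The sexes were next set against each other on the same day after paclitaxel. In paw on day 2 hair genes ran far higher in males: Krt33a, Krtap7-1 and Krtap8-1 had up to 476, 481 and 385 reads in males and 0 in females, at least 86.9-fold, 86.1-fold and 67.2-fold more (adjusted p = 0.00147, 0.000775 and 0.00217). Of 26 hair genes 21 were higher in males (23 over the list alone, median 4.29, also at the bound, camera adjusted p = 1.41e-08, 0.989 with an estimated correlation). Matrix genes were higher in 12 of 29 cases (14 over the list alone, median 0.60, camera adjusted p = 0.00187, 0.989 with an estimated correlation), with Bgn at 1.65 ± 0.22 (adjusted p = 1.41e-05) and Col3a1 at 1.40 ± 0.31 (adjusted p = 0.00201). Respiration genes were lower in 21 of 32 cases and higher in 1 (25 and 1 over the list alone, median -0.60, camera adjusted p = 7.82e-07, 0.989 with an estimated correlation), with Cox4i1 at -1.1 ± 0.14 (adjusted p = 1.39e-05). The mean skeletal muscle level was 7.44 log2 CPM in males and 9.52 in females (median -1.36), and bone and cartilage had a median of -0.50. With the muscle level as a covariate the medians were 4.16 for hair, 0.75 for matrix and -0.49 for respiration genes. Of the sex-linked genes, Ddx3y and Eif2s3y were at least 826-fold and 729-fold higher in males, and Xist, which shares bases with the opposite-strand Tsix, gave -9.95 ± 0.27 (adjusted p = 7.85e-15). The 5 sex-linked genes passed as a list (camera adjusted p = 1.47e-37, 6.09e-08 with an estimated correlation) but not by DESeq2 (adjusted p = 0.666). In all, 2413 genes were higher and 2381 lower in males, and 1891 differed with the groups fitted alone.

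On day 6 the male paw held more of the macrophage genes, with Cd68 1.59 ± 0.26 higher (adjusted p = 0.000103), Itgam of myeloid cells 1.2 ± 0.26 (adjusted p = 0.00128) and 14 of 25 list genes higher (15 over the list alone, median 1.08, camera adjusted p = 0.000175, 0.907 with an estimated correlation). Langerhans cell Cd207 was lower in males (-1.34 ± 0.27, adjusted p = 0.000814). Matrix genes were higher in 25 of 29 cases (26 over the list alone, median 1.28, camera adjusted p = 5.53e-11, 0.653 with an estimated correlation), including Bgn (1.93 ± 0.22, adjusted p = 2.19e-06) and Mmp2, which cuts matrix (1.26 ± 0.18, adjusted p = 2.58e-05). Hair genes were higher in 15 of 26 cases (19 over the list alone, median 3.35, camera adjusted p = 0.000415, 0.907 with an estimated correlation) and immediate early genes in 6 of 15 with 1 lower (6 and 1 over the list alone, median 0.78, camera adjusted p = 0.0494, 0.907 with an estimated correlation). Among the latter were Fos (2.97 ± 0.61, adjusted p = 0.000861) and Egr1 (2.15 ± 0.41, adjusted p = 0.000446). Replication genes were lower in 13 of 26 cases (13 over the list alone, median -0.53, camera adjusted p = 0.00117, 0.907 with an estimated correlation), with Gins1 at -1.02 ± 0.22 (adjusted p = 0.00147), and respiration genes in 15 of 32 with 1 higher (17 and 1 over the list alone, median -0.53, camera adjusted p = 0.000161, 0.907 with an estimated correlation). Cholesterol synthesis genes were lower in 9 of 24 cases (9 over the list alone, median -0.32, camera adjusted p = 0.0161, 0.946 with an estimated correlation, 0.201 with muscle as a covariate), among them Acat2 (-1.01 ± 0.22, adjusted p = 0.00128) and Idi1 (-0.93 ± 0.21, adjusted p = 0.0017). The mean skeletal muscle level was 7.55 log2 CPM in males and 4.53 in females, and bone and cartilage 3.16 and 0.7. With the muscle level as a covariate the medians were 0.69 for macrophage, 1.16 for matrix, 3.73 for hair, 0.83 for immediate early, -0.34 for replication, -0.67 for respiration and -0.16 for cholesterol synthesis genes. The covariate did not even out bone and cartilage genes, whose median was 2.29 without it and 2.36 with it. In all, 2767 genes were higher and 2953 lower in males.

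In DRG on day 2 males held more ion channel transcripts than females, 19 of 30 with 1 lower (20 and 1 over the list alone, median 0.44, camera adjusted p = 0.000227, 0.126 with an estimated correlation). Among these were Scn10a (0.77 ± 0.10, adjusted p = 1.69e-05), Cacna1a (0.59 ± 0.05, adjusted p = 2.31e-07) and the potassium channel gene Kcnd3 (0.73 ± 0.09, adjusted p = 1.95e-05). Sprr1a, a small proline-rich protein gene induced in injured sensory neurons, had up to 363 reads in males and at most 12 in females (4.56 ± 0.83, adjusted p = 0.000436). Neutrophil genes were higher in 9 of 15 cases (11 over the list alone, median 0.96, camera adjusted p = 0.0467, 0.953 with an estimated correlation, 0.0891 with muscle as a covariate), among them Mmp8 (1.58 ± 0.33, adjusted p = 0.00133) and Lcn2 (1.41 ± 0.31, adjusted p = 0.00192). Keratinocyte genes were lower in 20 of 21 cases, over all genes and over the list alone (median -2.28, camera adjusted p = 4.97e-16, 0.049 with an estimated correlation), with Krt2 at -3.28 ± 0.18 (adjusted p = 7.68e-09). Respiration genes were lower in 26 of 32 cases and higher in 2, over all genes and over the list alone (median -0.41, camera adjusted p = 2.15e-07, 0.953 with an estimated correlation). Myh6 was 5.82 ± 0.56 higher (adjusted p = 1.71e-06). In all, 3775 genes were higher and 3845 lower in males. The ion channel, keratinocyte and respiration lists had moved in the opposite direction in treated females against vehicle. Male DRG on day 2 differed from vehicle females, in the same library set, in 49 genes, so these differences cannot be assigned to sex.

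On day 6 male DRG still held more Scn10a (0.38 ± 0.10, adjusted p = 0.00522) and Cd68 (0.79 ± 0.22, adjusted p = 0.00917) than female DRG, and Calca gave -0.12 ± 0.07 (adjusted p = 0.221). Keratinocyte genes were lower in 19 of 21 cases (20 over the list alone, median -1.82, camera adjusted p = 1.57e-12, 0.12 with an estimated correlation) and respiration genes in 20 of 32 with 1 higher (22 and 2 over the list alone, median -0.36, camera adjusted p = 5.56e-05, 0.98 with an estimated correlation). In all, 2835 genes were higher and 3376 lower in males, while male DRG on day 6 differed from vehicle females in 279 genes. Changes over time within each sex were then set against each other, which cancels a constant offset between the library sets. From day 2 to day 6 no gene passed in paw (0, with 1488 at unadjusted p < 0.05 and 15 by DESeq2) or in DRG (0, with 1536 at unadjusted p < 0.05 and 24 by DESeq2). Paw gave 12 genes without female day 2 replicate 1 and 2 without female day 6 replicate 2. DRG gave 6 without female day 2 replicate 3, 9 without female day 6 replicate 1, 432 without female day 6 replicate 3, and 2 with no low-count filter or with muscle as a covariate.

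For the later span, day 15 in males and 16 in females against day 2, sex by time gave 1 gene in paw, with 1332 at unadjusted p < 0.05 and 97 by DESeq2. Adh7, an alcohol and retinol dehydrogenase gene of epithelia, had a male change minus female change of -1.17 ± 0.18 (adjusted p = 0.0363). The call was lost without male day 2 replicates 2 or 3, without female day 2 replicates 2 or 3 and without any library of male day 15 or female day 16. Without female day 2 replicate 1 the comparison called 183 genes, with relative-log-expression size factors 0, with muscle as a covariate 3, and with the groups fitted alone 0. Hair genes had the widest difference as a list, a median of -3.45 (0 called, 13 over the list alone, camera adjusted p = 4.7e-21, 0.464 with an estimated correlation), where the mean list level went from -0.75 to 3.54 log2 CPM in females and from 3.65 to 4.65 in males. In all, 13 lists passed here. In the earlier span 17 passed in paw, among them replication genes (median -0.62, 0 called, 8 falling over the list alone, camera adjusted p = 3.54e-13, 0.517 with an estimated correlation), and 8 in DRG, among them myelinating Schwann cell genes (median -0.27, 0 called, 6 falling over the list alone, camera adjusted p = 1.07e-08, 0.443 with an estimated correlation). None of these lists passed with an estimated correlation.

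Treated males were also compared with vehicle females, in which sex differs along with treatment. Both lie in the set with more reads on several genes, but in paw they were not alike. Reads that touched more than 1 gene made up 0.58% to 0.63% in vehicle and 0.54% to 0.57% in males, and reads outside genes 20.05% to 21.55% and 17.54% to 19.55%, whereas in DRG the ranges overlapped. Collagen genes were higher in male paw. On day 2 Col1a1 was 2.67 ± 0.36 higher (adjusted p = 0.000411), Col3a1 2.37 ± 0.32 (adjusted p = 0.000411) and Sparc 1.77 ± 0.21 (adjusted p = 0.000107), and 20 of 29 matrix genes were higher (22 over the list alone, median 1.27, camera adjusted p = 4.12e-30, 0.0429 with an estimated correlation). Macrophage genes were higher in 4 of 25 cases (14 over the list alone, median 1.00, camera adjusted p = 4.93e-10, 0.777 with an estimated correlation), with Cd68 at 1.56 ± 0.25 (adjusted p = 0.00182, lost with the groups fitted alone). Cd207 was lower (-1.56 ± 0.27, adjusted p = 0.00305). Col1a1 stayed 2.39 ± 0.36 higher on day 6 (adjusted p = 0.000936) and 2.36 ± 0.36 on day 15 (adjusted p = 0.00191), and 15 and 17 of 29 matrix genes were higher (25 and 23 over the list alone, medians 1.15 and 1.07, camera adjusted p = 1.25e-22 and 1.99e-25, adjusted p = 0.119 and 0.0823 with an estimated correlation). The content of the biopsies differed too. On days 2, 6 and 15 bone and cartilage genes had medians of 0.95, 1.54 and 0.82 and skeletal muscle genes 0.3, -0.28 and 0.86. With the muscle level as a covariate the matrix medians were 1.19, 1.06 and 0.9. Bone and cartilage medians were then 0.8, 1.58 and 0.14, so on days 2 and 6 the covariate did not even out that content. The retinal oxidase gene Aox4 was 2.94 ± 0.39 and 2.77 ± 0.38 higher on days 2 and 6 (adjusted p = 0.000295 and 0.000517), and the serpin gene Serpinb6e fell by 4.78 ± 0.60, 4.07 ± 0.57 and 5.17 ± 0.62 on the 3 days (adjusted p = 0.000181, 0.000517 and 0.000178).

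These male paw comparisons called 913, 916 and 676 genes on days 2, 6 and 15, and 1532, 1418 and 1120 by DESeq2. On day 2 vehicle replicates 1, 2 and 3 and male replicate 1, each left out, gave 606, 340, 359 and 337. On day 6 the same vehicle libraries gave 491, 356 and 324, and male replicates 1 and 2 gave 335 and 302. On day 15 they gave 324, 126 and 218, and male replicates 1 and 3 gave 136 and 158. Muscle as a covariate gave 1400 on day 2 and 1386 on day 6, and the groups fitted alone gave 156 on day 2. In DRG clock genes were among those called. On day 2 Per3 was 1.33 ± 0.12 higher (adjusted p = 6.3e-05), its partner Per2 1.2 ± 0.17 (adjusted p = 0.00391) and Arntl, which encodes an activator of the clock, fell by 1.73 ± 0.15 (adjusted p = 2.41e-05). Of 18 clock genes 6 rose and 1 fell (11 and 3 over the list alone, median 0.39, camera adjusted p = 1.09e-16, 0.000989 with an estimated correlation). Ctss fell by 0.87 ± 0.09 (adjusted p = 0.000176). The injury genes Ecel1 and Sprr1a rose by 2.76 ± 0.44 and 4.23 ± 0.79 (adjusted p = 0.0155 and 0.0355), calls lost without vehicle replicates 1 or 2 or male replicates 2 or 3, and for Sprr1a also without vehicle replicate 3 and with the groups fitted alone. The count was 49 (22 up and 27 down), against 192 by DESeq2, 123 with the groups fitted alone, and 20, 27, 18 and 26 without vehicle replicate 2 or male replicates 1, 2 and 3.

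Male DRG on day 6 differed from vehicle females in 279 genes, 110 up and 169 down. The neurofilament gene Nefh was 0.31 ± 0.04 higher (adjusted p = 0.00455), while the collagen VI genes Col6a1 and Col6a2 fell by 0.78 ± 0.09 and 0.69 ± 0.09 (adjusted p = 0.000534 and 0.0025). Matrix genes fell in 6 of 28 cases (21 over the list alone, median -0.59, camera adjusted p = 6.59e-24, 0.0195 with an estimated correlation). Antigen presentation genes fell in 5 of 15 cases (9 over the list alone, median -0.73, camera adjusted p = 1.38e-11, 0.0281 with an estimated correlation). Genes of other cells were lower too, with mean levels of 2.04 against 3.31 log2 CPM in vehicle for adipocytes, 3 against 3.9 for red blood cells and 2.24 against 2.68 for mast cells. Clock genes rose in 8 and fell in 3 of 18 cases (11 and 3 over the list alone, median 0.39, camera adjusted p = 3.45e-10, 0.00648 with an estimated correlation). Tubulin genes had a median of 0.15 (1 called, 5 rising over the list alone, camera adjusted p = 0.000631, 0.0607 with an estimated correlation). The count was 766 by DESeq2 and 891 with the groups fitted alone. It was 96, 27 and 145 without vehicle replicates 1, 2 and 3, and 44, 180 and 27 without male replicates 1, 2 and 3.

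Agreement between comparisons was measured as the correlation of log2 changes, beside values simulated with shared controls and no effect. Within female paw the 6 pairs of days correlated at 0.57 to 0.81, where shared controls alone gave 0.50. Over genes with a mean log2 CPM of at least 1 they correlated at 0.50 to 0.77. The lowest, days 6 and 16, equalled its simulated 0.50, with a covariance of 0.132 beside a simulated 0.046. Days 2 and 6 gave 0.71 with a covariance of 0.554 (simulated 0.065), or 0.52 over genes with a mean log2 CPM of at least 1, and shared 1446 rises and 1431 falls, where independence would give 346.9 and 308.4. In female DRG, days 2 and 6 gave 0.90 with a covariance of 0.541 (simulated 0.027) and shared 3258 rises and 2330 falls (933 and 684.8 under independence). Part of that excess may come from the shared vehicle libraries. Paw and DRG share no library, and female changes correlated between them at 0.62 on day 2 (covariance 0.342, simulated 0), with 1663 shared rises and 1313 shared falls (575.9 and 506.1 under independence), and at 0.60 on day 6 (1888 and 1184, against 584.1 and 360.5). All these female comparisons cross between the library sets, and the simulations held no offset between sets, which would also give such correlations. Between tissues, males against females on day 2, which also cross sets, correlated at 0.67. Males against vehicle females on day 2, within 1 set, correlated at 0.22 (0.04 over genes with a mean log2 CPM of at least 1). Male and female changes from vehicle correlated at 0.11 in paw on day 2, below the simulated 0.51, with a covariance of 0.056 beside a simulated 0.064. In DRG on day 2 the correlation was 0.20, below the simulated 0.49, with a covariance of 0.056 beside a simulated 0.027. There 12 rises and 15 falls were shared (5.7 and 6.5 under independence).

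Genes called in the same direction in every treated group against vehicle females were picked out after their values were seen. All comparisons of a tissue used the same 3 vehicle libraries, so a deviation of those libraries alone would be shared by all groups. In DRG 7 genes rose and 11 fell in all 4 groups, where independence of the sexes would give 4 and 3.6. Calca rose by 0.37 to 0.56, the growth cone gene Gap43 by 0.33 to 0.38 and Nefh by 0.25 to 0.36. The antigen presentation genes H2-Aa and H2-Ab1 fell by 0.48 to 0.86 and by 0.36 to 0.85, Ctss by 0.28 to 0.90, C1qb by 0.34 to 0.72 and Bgn by 0.68 to 1.13. In paw 25 genes rose and 18 fell in all 7 groups, against 13.6 and 6.5. Gap43 rose by 0.98 to 1.55, the potassium channel subunit gene Kcnmb4 by 1.11 to 1.48 and Adh7 by 0.44 to 1.59, while P2rx2, an ATP receptor gene, fell by 0.76 to 1.63. Clock genes appeared in both tissues. Tef, a clock output gene, rose by 0.42 to 1.08 in paw and by 0.38 to 0.53 in DRG, and Arntl fell by 0.49 to 1.09 in paw and by 0.95 to 1.77 in DRG. Dbp, another output gene, rose by 1.2 to 2.78 in paw and by 2.34 to 3.35 in DRG, although it shares bases with the opposite-strand Sphk2.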

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

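All tests of overlap, shared effect, carry-over and clock phase below, and the comparisons among female days and of treated males with vehicle females with their splits, were chosen after the results were seen. The other comparisons and splits were planned before. Between the sexes, 4794 and 5720 genes differed in paw on days 2 and 6 and 7620 and 6211 in DRG, by direct tests of male against female libraries. Other splits of the same 6 libraries gave at most 1, 0, 0 and 1 genes. Among treated female days, direct tests gave 134 genes in paw for day 6 against day 2, 227 for day 16 against day 2 and 163 for day 26 against day 16, where other splits gave at most 70, 2 and 0. In DRG day 6 against day 2 gave 28 genes, and 3 of the 10 splits gave as many, the highest 1671, which points to a structure of the samples that is not the day. Tests of sex by time gave 17 gene lists in paw and 8 in DRG from day 2 to day 6, and over the later span 13 lists and the gene Adh7, with a male change minus female change of -1.17. None of these lists passed with an estimated correlation. Over the earlier span the real count was 0 in paw and in DRG, so all 100 splits drawn gave as many by design and decide nothing, the highest giving 4404 and 4720. Over the later span 10 of 100 gave at least the 1 gene seen, the highest 2921. Those splits mix sexes and library sets, and their counts point to that structure of the samples.

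For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. Against vehicle the real counts, with the highest other split, were 4454 (0), 4527 (0), 3331 (0) and 3133 (0) for female paw on days 2, 6, 16 and 26, and 7758 (0) and 6469 (0) for female DRG on days 2 and 6. Treated males against vehicle females gave 913 (0), 916 (0) and 676 (0) in paw and 49 (0) and 279 (2) in DRG. In each of these, 1 split, the real one, gave as many genes. For paw male days 6 and 15 against day 2 (0 real, 1 and 0 the highest other), DRG male day 6 against day 2 (0 and 0) and paw female day 26 against day 2 (0 and 0), all 10 splits gave as many by design, which decides nothing.

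The first pattern weighed was the size of the difference between treated female and vehicle libraries. Reads counted differently at genes with exons on both strands may explain part of it: in DRG on day 2, 6% of genes with opposite-strand overlap changed by more than 1 log2 against 3.43% of genes with none, a ratio of 1.75. Other comparisons across the sets gave 1.7 to 2.5 in paw of females against vehicle and only 1.36 and 1.23 in paw of males against females, while within 1 set males against vehicle females gave 2.86 and 3.12 in DRG, from 3 and 6 such genes, and 0.4 to 0.46 in paw. Overlap of the exons compared here cannot explain it all, since 72.2% of the called genes had no annotated overlap. Among all DRG genes with a mean log2 CPM of at least 1, 9728 of 13156 had none. Introns, and exons of genes absent from the count files, were not compared, so opposite-strand reads from those are not excluded. An effect of paclitaxel alike in both sexes was argued against as the source of most of the female difference from vehicle. Beyond shared controls, male and female changes from vehicle on day 2 shared a covariance of 0.029 in DRG over all tested genes. That was 5.6% of the 0.514 shared by female days 2 and 6. In paw on day 2 it was -0.008 (-1.6% of 0.489). Before that subtraction, paw on day 2 gave 0.06 beside a simulated 0.046 over genes with a mean log2 CPM of at least 1. Over all tested genes, the later paw days (female 16, male 15) gave 0.133 beside 0.064. Day 6 gave 0.047 beside 0.064 in paw and 0.049 beside 0.027 in DRG. Female days also share any offset between the sets, so these percentages do not measure a smaller effect common to both sexes. What stays open is a difference between sets of libraries made or processed apart, or an effect of paclitaxel in females alone. Either could come with a smaller effect common to both sexes. The highest share of ambiguous reads among treated females was 0.3%, below every other library. As no treated female lies in the other set, these explanations cannot be told apart.

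The second pattern was skin keratin genes in DRG of treated females. Reads carried between paw and DRG libraries of the same set may explain it: 62 genes over 300 CPM in paw and under 1 CPM in vehicle DRG gained a median of 1.41 and 1.4 per 1000 of the paw level on days 2 and 6, and all 62 gained. In the other direction, 46 genes over 200 CPM in DRG and under 1 CPM in vehicle paw gained at least 0.43 per 1000 in each treated female paw group (0.43 to 0.68) and -0.09 to 0 in male paw. The paw and DRG levels used to pick both sets of genes were means of the treated female groups. A gene raised throughout treated females could thus be picked and gain without carry-over, and no such selection was made in males. A first test on sensory neuron lists gave medians of -0.85 to 0.69 in treated female paw and was replaced, because paw expresses many of those genes itself. Paclitaxel raising keratin genes in DRG of both sexes was argued against by a highest median gain of 0.13 per 1000 in male DRG, beside 1.42 and 1.4 in females.

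The third pattern was clock genes, which differed from vehicle in treated groups of both sexes and tissues. A shift in clock phase may explain it: over 13 genes and 11 comparisons, 81.1% of values had the output genes higher and the opposite arm lower (61.5% to 100% per comparison), and the highest of 1000 draws of 13 genes of like expression in the same comparisons gave 69.9%. The comparisons of a tissue share their 3 vehicle libraries and so are not independent, and random genes are not regulated together as clock genes are. The 13 genes come from the clock list fixed beforehand, but include Tef, Dbp and Arntl, which had been noticed for moving this way in every comparison. The random draws carry no such selection. Called genes lay in both arms in both tissues, in 11 of the 11 comparisons. That count was fixed beforehand, as Tef and Dbp of the output arm and Arntl of the opposite arm had been picked for being called in every comparison. It is therefore no separate test of a change in 1 arm alone. Whether the phase moved with the hour of collection, which the labels do not give, or with paclitaxel stays open, as vehicle tissue was taken 1 day after injection and no treated tissue was.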

How the results depend on the processing

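The muscle covariate, and every alternative for comparisons among female days and of treated males with vehicle females, were chosen after the results were seen, and the others were planned. The cause of the moves below was not tested. By DESeq2 the counts moved to 2 (paw male day 15 against day 2), 15 and 97 (paw sex by time, early and late), 24 (DRG sex by time), 9 (DRG male day 6 against day 2), 1463, 507 and 249 (paw female days 6, 16 and 26 against day 2), 409 (paw female day 26 against 16), 214 (DRG female day 6 against day 2), 1532, 1418 and 1120 (paw male days 2, 6 and 15 against vehicle females) and 192 and 766 (DRG male days 2 and 6 against vehicle females). With only the compared groups fitted they moved to 2019 (paw female day 2 against vehicle), 1891 (paw males against females on day 2), 1 (paw male day 15 against day 2), 0 (late sex by time), 0, 0 and 1 (paw female days 6, 16 and 26 against day 2), 0 (paw female day 26 against 16), 0 (DRG female day 6 against day 2), 156 (paw male day 2 against vehicle females) and 123 and 891 (DRG male days 2 and 6 against vehicle females). With the muscle covariate they moved to 3 (late sex by time), 0 (paw female day 6 against day 2), 355 (paw female day 26 against 16), 1400 and 1386 (paw male days 2 and 6 against vehicle females) and 2 (DRG sex by time). No low-count filter gave 47 for paw female day 6 against day 2 and 2 for DRG sex by time, and relative-log-expression size factors gave 0 for late sex by time.

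Leaving out 1 library gave 0 to 12 genes for early and 0 to 183 for late sex by time in paw and 0 to 432 in DRG. It gave 0 to 2063, 0 to 476 and 0 to 259 for paw female days 6, 16 and 26 against day 2, 12 to 111 for day 26 against 16, and 4 to 951 for DRG female day 6 against day 2. Treated males against vehicle females gave 337 to 721, 302 to 737 and 126 to 456 in paw on days 2, 6 and 15, and 18 to 65 and 27 to 180 in DRG on days 2 and 6. Female days against vehicle gave 3019 to 4787, 3445 to 4308, 2327 to 2753 and 2209 to 2612 in paw and 6621 to 7707 and 5343 to 6017 in DRG. Males against females gave 3588 to 4674 and 4427 to 5581 in paw and 6375 to 7521 and 5249 to 5675 in DRG. Male days against male day 2 gave 0 throughout.

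With the replicate number as a block, paw female day 6 against day 2 gave 566 genes and DRG female day 6 against day 2 gave 11. There the replicates share only a number, and 0 of the samples in either correlated best with its own number. In the comparisons whose replicates were paired by the values, the replicate block gave 4608 (paw female day 2 against vehicle), 1016, 982 and 733 (paw male days against vehicle females), 0 (DRG male day 6 against day 2) and 241 (DRG male day 6 against vehicle females). Over all comparisons it weakened 27 of 1442 named-gene results and 2 of 243 passing lists, none of them a result the report prints for a paired comparison.

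The correlation of paw female days 2 and 6 fell to 0.52 over genes with a mean log2 CPM of at least 1. For named genes, 17175 of 18329 alternative values gave the same call, 827 were weaker and 327 stronger. For passing gene lists 1469 of 1943 gave the same call and 474 were weaker, among them 225 of 243 with an estimated correlation and 169 with fry. No call changed direction.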

Other observations

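The muscle covariate, the pseudogene and overlap shares and the comparisons among female days and of males with vehicle females were chosen after the results were seen, and the day 2 lists against vehicle were planned. Hair genes in treated female paw had a mean level of -0.75 log2 CPM on day 2 and 3.54 on day 16, with standard deviations of 1.11 and 1.5 between libraries, while treated males had 3.65 on day 2. The hair cycle differs between animals and body sites, and a biopsy with or without growing follicles could give such values. Without female day 2 replicate 3 the count went from 227 to 0 for day 16 against day 2 and from 134 to 0 for day 6 against day 2.

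Skeletal muscle genes ran from a mean of 1.71 to 9.42 log2 CPM among the 3 vehicle paw libraries alone, which no treatment explains. Fitting that level as a covariate moved paw male day 2 against vehicle females from 913 to 1400 genes and day 6 against day 2 in females from 134 to 0. In female paw on day 2 against vehicle, the median changes of the fibroblast and macrophage lists were 0.72 and 0.56 without the covariate (camera adjusted p = 0.00168 and 0.0364, each 0.976 with an estimated correlation) and 0.48 and 0.28 with it (adjusted p = 0.108 and 0.445, in edgeR fits). The depth at which a punch is taken may account for part of those 2 lists.

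Tpt1 rose from at most 2 reads to 745 in female paw on day 2 and has 6 named pseudogenes, and Rpl37 rose by 3.71. Ribosomal and Tpt1-like sequences have many copies in the genome, so a change in how reads with several places were treated is a candidate explanation. In DRG on day 2, 10.85% of genes with a named pseudogene changed by more than 1 log2 against 3.43% of genes with no overlap, beside the ratio of 1.75 for opposite-strand overlap. The pseudogene share was 9.17% to 17.47% in comparisons of treated females with vehicle or males and 0% to 0.44% in males against vehicle females, where no-overlap genes gave 0.06% to 1.73%. Reads without a unique place were 45.18 to 48.61 per 100 unique in DRG of treated females and 48.78 to 51.04 in other DRG, but in paw the ranges overlapped (81.87 to 95.78 and 86.68 to 92.38). The deposited counts do not show how such reads were treated.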
